A study of Homo sapiens with 2 samples.

How the data were processed

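Total RNA of MCF-7 cells stably carrying an empty vector or MMP-14 cDNA was analysed after 48 h of monolayer culture, on 1 array per line, per the labels. The series design text gives RNA pooled from 3 biological replicates per line in monolayer, and the growth protocol in the labels describes several culture formats and another number of replicates; the design text was followed. The deposited values are MAS5 signal intensity on a linear scale, made with MAS5 in Affymetrix Expression Console per the submitters' processing notes; versions are not given in the sources used here. The 2% trimmed mean was 100.03 in both arrays, so the intensities had been scaled per array before deposit. MAS5 subtracts a mismatch-based estimate, which leaves dim probe sets with noisy values. Scanner files were not used here.

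The values were used as deposited and taken to log2. Of 22277 probe sets, 62 controls were set aside. The platform annotation gave 1 gene for 19064 of the other 22215, several genes for 1043 and none listed for 2108. Gene IDs of 19052 single-gene probe sets matched the reference table and 0 symbols changed. Probe sets with several genes or none listed were left out of the gene results, which leaves DDR1 without a value because its probe sets also carry MIR4640. Each gene was represented by its single-gene probe set with the highest mean log2 signal, and 1284 of 2335 genes with several detected probe sets had 1 sign in all of them.

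The floor was the 50th percentile of non-control probe sets in each array, and lower signals were set to it. Of 118 probe sets of tissue-restricted genes, 2 were above it. The log2 ratio is the array labelled MMP-14 minus the array labelled empty vector. A gene was counted when it was above the floor in at least 1 array and differed by at least 2-fold. A fold with 1 array at the floor is a lower bound. With 1 array per group there was no significance test and no leave-one-out, and the spread across genes is not an error of the groups.

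The design, the 32 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes MMP14; the 12 largest increases and 12 largest decreases among genes above the floor in both arrays, at least 2-fold different, with 1 sign over detected probe sets; the 5 brightest bounded genes per direction; up to 4 members per list with the largest log2 ratios; and BIK, DDR1, TIMP2, MMP2, ESR1, CDH1 and VIM. A list's median over detected members was placed among the medians of 10000 random lists of the same size, matched on mean log2 signal in 20 bins, if at least 5 members were detected. Percentiles below 2.5 or above 97.5 count as standing apart.

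The error that the arrays themselves give is the SD of log2 ratio between 2 probe sets of a gene, 0.20, which holds no biological or between-hybridisation spread. The robust SD of log2 ratios was 0.31 in the dimmest decile of genes and 0.12 in the brightest. In data simulated from this comparison (6845 genes), the 2-fold rule was tried on 50 genes per size of change. It called 8% of genes changed by 1.5-fold, 46% of those changed by 2-fold, 98% by 3-fold and 100% by 4-fold. It also called 7 of the 6645 other genes, 29 of which carried the shift of the simulated list. The noise was normal, drawn independently per probe set with the robust SD of its signal decile. It lacks heavier tails, so those 7 calls give no error rate for the real genes called. A simulated list shifted by -0.3 had a median of -0.27 at percentile 0, and an unshifted list lay at percentile 66.8.

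Alternatives were quantile normalization, median centring, loess on intensity (span 0.4), floors at the 40th and 60th percentiles, a floor at the 90th percentile of tissue-restricted probe sets, no floor, the floor added as an offset, the median over probe sets, leaving out probe sets with the suffix _x_at or _s_at, thresholds of 1.5-fold and 3-fold, random lists not matched on signal, and, chosen after seeing the data, lists without members shared with the estrogen receptor list and the median over detected probe sets. The latter was added because the median over all probe sets takes undetected probe sets at the log2 difference between the floors, 0.06. Gene order for neighbouring genes came from a GRCh38.p14 gene table; no coordinates are given because no build is named for the arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.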

Results

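Gene expression was measured in MCF-7, a human breast adenocarcinoma line of luminal, estrogen receptor-positive character. Cells stably transfected with an empty vector were set against cells stably transfected with MMP-14 cDNA, which encodes MT1-MMP, a membrane-anchored collagenase. Both lines were grown as monolayers for 48 h. Per the series design text, RNA from 3 biological replicates was pooled per line, while the growth protocol in the labels, which covers several culture formats, gives another number of replicates. Each line was hybridised to 1 array, so there were no replicates and no difference could be tested; the number of arrays limits the precision of every value. Each array gave MAS5 signals for 22277 probe sets, with a median of 21.3 in the array labelled empty vector and 22.3 in the array labelled MMP-14. Of 11963 genes, 6684 and 6681 were above the detection floor (signals of 21.1 and 22.1). Across genes above the floor in both arrays, log2 signals had a Pearson correlation of 0.985. Genes are not independent replicates. The only error the values give is technical: log2 ratios of 2 probe sets of the same gene differed with an SD of 0.20 per probe set over 2172 genes. Both probe sets lie on the same arrays, so this SD holds no biological or between-hybridisation spread.

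The transfected gene was examined first, as a check of the labels. None of the 4 MMP14 probe sets was above the floor in either array. The brightest read 16.8 in the array labelled empty vector and 17.4 in the array labelled MMP-14, and the others were all below 2. The positions of the probe sets within the transcript are not given in the sources used here, so it is unknown whether they can detect the transfected cDNA. The arrays therefore give no sign that the labels match their contents, and every direction below is that of the array labelled MMP-14 relative to the array labelled empty vector. MMP2, a gelatinase that MT1-MMP activates, read 9.04 and 3.57, and TIMP2, the inhibitor that takes part in that activation, read 12.1 and 18.1, all below the floor.

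The comparison asks which genes differ in expression between MCF-7 cells with and without MMP-14. In the array labelled MMP-14, 24 genes were at least 2-fold higher and 42 at least 2-fold lower, out of 6860 genes above the floor in at least 1 array. With signals at or below the floor set to it, which bounds the fold of some genes, 8 genes were at least 3-fold lower and 0 at least 3-fold higher. These counts read each gene at its brightest probe set. For example, other probe sets of GALC (log2 ratio 1.89) and TIMP3 (1.71) were over 3-fold higher, and another of ALDH3B2 (-1.69) over 3-fold lower. Outside the gene counts, probe sets 213711_at (2.29) and 210299_s_at (1.61) were over 3-fold higher and 218559_s_at (-1.62) over 3-fold lower. GJA1, a gap junction protein, had the largest decrease among genes above the floor in both arrays, at 45.9 against 340 (log2 ratio -2.89, 7.40-fold lower). Of 29 estrogen receptor targets 23 were lower, with a median log2 ratio of -0.29. GALC, TIMP3 and EDN1 headed the higher genes among those above the floor in both arrays.

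After GJA1, TNFRSF11B, the decoy receptor osteoprotegerin, read 24.0 against 142 (log2 ratio -2.57, with -1.71 at its other probe set). PDZK1, a scaffold protein of membrane transporters, read 25.6 against 128 (-2.32). The sulfate transporter SLC26A2 read 97.4 against 393 (-2.01), and MGP, an inhibitor of matrix calcification, read 211 against 815 (-1.95). The chloride channel protein CLIC3 (-1.87), the retinoic acid hydroxylase CYP26B1 (-1.75), the kallikrein KLK11 (-1.59) and ASS1, an arginine synthesis enzyme (-1.58), followed. AGR2, a protein disulfide isomerase of secretory epithelium and the brightest of these genes, read 858 against 2462 (-1.52). The small heat shock protein HSPB8 (-1.50) and the transcription factor EGR3 (-1.47) completed the 12 largest decreases among genes above the floor in both arrays whose probe sets shared a sign. All of them but TNFRSF11B had 1 single-gene probe set, so they met the shared sign by construction.

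The highest of the 12 largest increases was GALC, a lysosomal galactosylceramidase, at 1296 against 439 (log2 ratio 1.56, with 1.89 at its other probe set). TIMP3, a matrix-bound inhibitor of metalloproteinases, read 337 against 120 (1.49, and 1.01 to 1.71 over 4 probe sets). EDN1, the endothelin precursor, read 121 against 44.8 (1.43). LDLRAD4, an inhibitor of TGF-beta signalling, had a log2 ratio of 1.42, SPATA7 of 1.39, and the prostaglandin E receptor PTGER4 and the retinaldehyde dehydrogenase ALDH1A3 of 1.30 each. GABPB1-IT1 (1.19), the coagulation inhibitor TFPI (1.17, and down to 0.76 over 3 detected probe sets), RAB11FIP3 (1.17, with 0.60 at its other probe set), the TGF-beta target PMEPA1 (1.13) and the cholesterol acyltransferase SOAT1 (1.12) made up the rest. EDN1, SPATA7, ALDH1A3, GABPB1-IT1, PMEPA1 and SOAT1 rested on 1 detected probe set each. Of the 12 largest changes in each direction, LDLRAD4, ALDH1A3, GABPB1-IT1, PMEPA1, SOAT1 and EGR3 were under 2-fold both with the floor at the 60th percentile and with the floor added as an offset, KLK11 in the first setting and TFPI in the second. The folds in the first setting are bounds, as the dimmer signal of each gene named for it was below that floor (43.4 and 44.0). GABPB1-IT1, TFPI and RAB11FIP3 were under 2-fold with the median over probe sets, and TFPI and RAB11FIP3 with the median over detected probe sets, at 0.96 and 0.88. Several of the increases were dim in the array labelled empty vector, between 22.4 and 36.8 for GABPB1-IT1, ALDH1A3, LDLRAD4, PMEPA1 and SOAT1. Several of the decreases were dim in the array labelled MMP-14, whose floor was 22.1. There TNFRSF11B, PDZK1, EGR3, KLK11 and CYP26B1 read between 24.0 and 31.2.

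**Figure D1:**
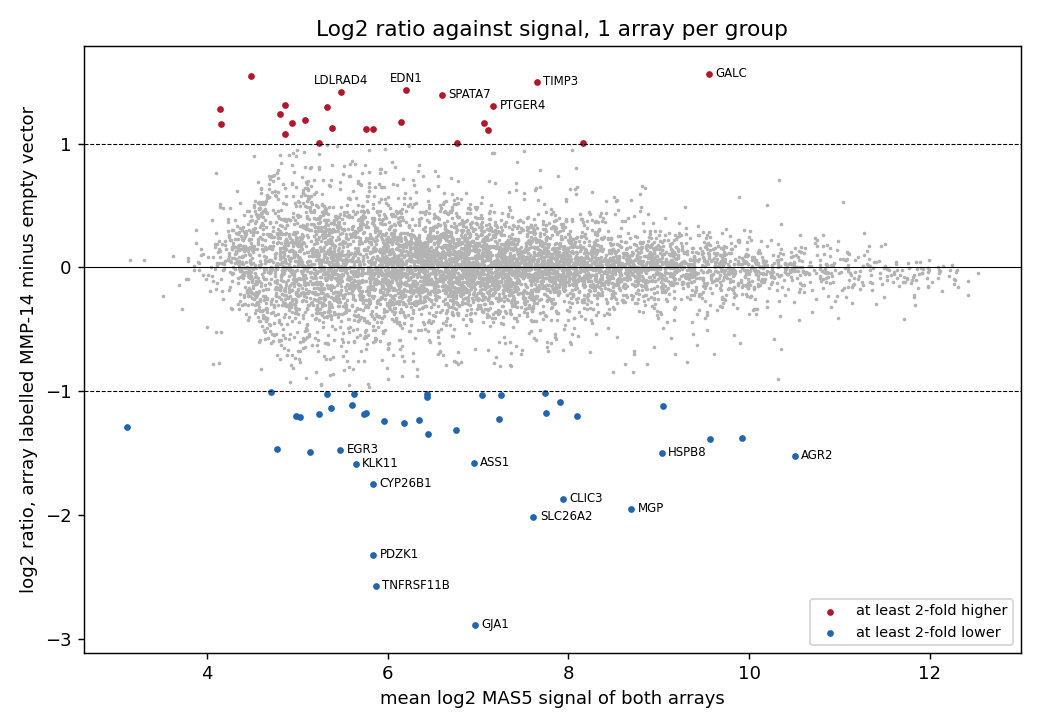
Log2 ratio of each gene (array labelled MMP-14 minus array labelled empty vector) against the mean log2 MAS5 signal of both arrays; each point is a gene above the floor in at least 1 array, and dashed lines mark a 2-fold difference. Signals at or below the floor are set to it in the ratio; GJA1 lies at -2.89, and GALC at 1.56 is the brightest of those labelled above the upper line.

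In 7 of the higher and 6 of the lower genes, 1 array was at or below the floor, so the fold is a bound. MME, the membrane metalloendopeptidase neprilysin, was at least 2.92-fold higher, the sodium channel subunit SCNN1A at least 2.48-fold, HLA-F-AS1 at least 2.42-fold, the receptor ERBB4 at least 2.36-fold and NXN at least 2.24-fold. The spermine oxidase SMOX was at least 2.82-fold lower, TRIM29 at least 2.76-fold, the desmosomal plakophilin PKP1 at least 2.44-fold, the ecto-nucleotidase NT5E at least 2.31-fold and MPPED2 at least 2.30-fold. The median over all probe sets of TRIM29 was 0.06, because its undetected probe sets enter at the log2 difference between the floors. MME, SCNN1A, ERBB4, SMOX, PKP1 and MPPED2 were also under 2-fold with that median. Each rested on 1 detected probe set of 2 or 3, and the undetected ones enter the same way. With the floor at the 60th percentile (43.4 and 44.0) the bounds of these 10 genes were all under 2-fold. Their brighter signals were at most 62.1, so that floor allowed no larger bound and does not show a smaller fold. Among genes named below, CD44, LAMB3 and EPHA4 were under 2-fold with that floor, again as bounds, or with the floor added as an offset. TGFBI and JAG1 were under 2-fold with the offset. CD44, CELSR2 and JAG1 were under 2-fold with the median over probe sets, and CD44 and CELSR2 also with the median over detected probe sets. CD44 was under 2-fold without _x_at and _s_at probe sets too. The counts depended on the floor: at the 60th percentile 10 genes were higher and 27 lower, and at the 40th 51 and 74.

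Of 32 gene lists, 27 had at least 5 members above the floor. The medians of 8 lay outside the central 95% of 10000 random lists matched on signal, 1 of them higher and 7 lower. By chance 1.35 would fall outside if list members varied independently, like randomly drawn genes. Members that vary together would raise that number, whatever made the 2 arrays differ. These percentiles describe the pair of arrays and are not p-values.

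Estrogen receptor targets were the list with the lowest percentile. Of 29 detected members 23 were lower and 6 higher, 5 of them at least 2-fold lower and 0 at least 2-fold higher, with a median log2 ratio of -0.29 (percentile 0). PDZK1, HSPB8 and EGR3 were joined by the cadherin CELSR2 (-1.12 and -0.84 at 2 probe sets). ESR1, the estrogen receptor itself, read 497 against 668 at its brightest probe set (-0.43), but its 6 detected probe sets disagreed, from -0.51 to 0.24. Luminal markers had a median of -0.13 (percentile 0.06), with 18 of 25 lower, led by AGR2; ELF3 read -0.58 and -0.11 at 2 probe sets, and KRT7 at 0.76 and TFF3 at 0.47 went the other way. TFF1, TFF3 and XBP1 are in both lists. Basal markers were also lower, with a median of -0.31 (percentile 0.04) and 7 of 10 lower: the laminin chain LAMB3 had a log2 ratio of -1.02, CAV1 of -0.72 and ACTA2 of -0.71. With the median over all probe sets of each gene the basal list was at -0.12 (percentile 2.79), inside the central 95%, and with the median over detected probe sets, a setting chosen after seeing the data, at -0.38 (percentile 0). E-cadherin, CDH1, read 1768 against 1915 (-0.12). Vimentin, VIM, was below the floor in both arrays, at 7.96 and 3.86.

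Cholesterol and fatty acid synthesis genes were lower in 16 of 22 members, none by 2-fold, with a median of -0.17 (percentile 0.01). The fatty acid elongase ELOVL6 had a log2 ratio of -0.77, MVD of -0.59, IDI1 of -0.50 and SQLE of -0.42. Of 23 p53 targets 19 were lower, none by 2-fold, with a median of -0.21 (percentile 0.04). Among them were GADD45A (-0.94), the death receptor FAS (-0.84, and -1.14 to -0.44 over 4 probe sets), PLK2 (-0.70) and GDF15 (-0.39). S100 and annexin genes had 13 of 16 members lower and a median of -0.19 (percentile 0.01), with S100A14 at -0.67, ANXA6 at -0.61 and S100A10 at -0.41, while S100P was at 0.46. Extracellular matrix structural genes had 8 of 11 lower and a median of -0.24 (percentile 0.5), with COL4A5 at -0.71 and LAMB1 at -0.36. The matrix glycoprotein THBS1 was at 0.85, and COL5A1 probe sets disagreed, from -0.41 to 0.88. The matrix median moved to -0.12 (percentile 4.70) with a floor taken from tissue-restricted genes.

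TGF-beta and SMAD targets were the list that lay higher, with 14 of 24 members higher, 2 of them at least 2-fold, and a median of 0.16 (percentile 99.78). PMEPA1 was followed by TGFBI, a secreted matrix protein, at 1.11 and BMP7 at 0.95. ID4 read -0.79 at its brightest probe set and up to 0.05 at others. This result rested on the choice of probe sets: the list was at 0.08 (percentile 92.9) with the median over detected probe sets, and at -0.01 (percentile 44.6) without _x_at and _s_at probe sets, which left 12 members. With the median over all probe sets it was at 0.06 (percentile 87.0), the log2 difference between the floors.

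**Figure D2:**
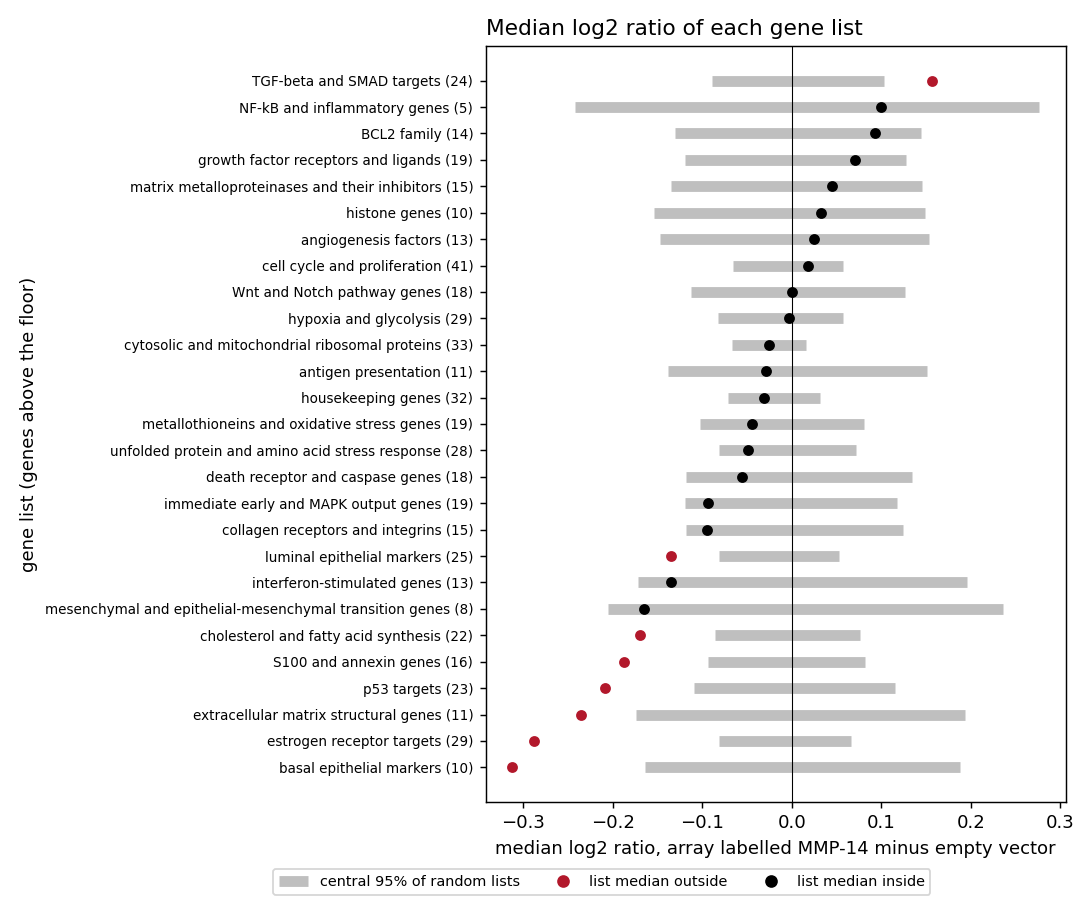
Median log2 ratio (array labelled MMP-14 minus array labelled empty vector) of each of the 27 gene lists with at least 5 detected members, whose number is in parentheses; grey bars span the central 95% of 10000 random lists and red points lie outside. Estrogen receptor targets lie at -0.29 against a random range of -0.08 to 0.07, and TGF-beta and SMAD targets at 0.16 against -0.09 to 0.10.

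Matrix metalloproteinases and their inhibitors lay inside the random range, with 8 of 15 members higher and a median of 0.05 (percentile 73.7) that was -0.02 under median centring, which shifts every log2 ratio by -0.06 and leaves percentiles as they are. After TIMP3, ADAM9 was at 0.61 and RECK at 0.41, and MMP15, at the floor in the array labelled MMP-14, was at least 1.35-fold lower. Collagen receptors and integrins had 10 of 15 lower and a median of -0.09 (percentile 5.45). The hyaluronan receptor CD44 was at -1.11 (-1.11 to -0.28 over 6 probe sets), ITGA3 at -0.94 and SDC1 at 0.32. With 3 other floors, or none, this list lay outside the random range, with medians of -0.13 to -0.17, but it was at 0.01 (percentile 42.1) with the median over probe sets and at -0.01 (percentile 41.4) without _x_at and _s_at probe sets. No probe set carries DDR1, a collagen receptor kinase, alone, so no gene value is given for it. The 4 probe sets that carry it with MIR4640 were above the floor in both arrays, with log2 ratios of -0.20 to -0.04. The BCL2 family had 9 of 14 higher and a median of 0.09 (percentile 90.04). BIK, a pro-apoptotic member, read 61.5 against 36.9 (0.74, 1 probe set), BCL2 was at -0.87, and BAX probe sets disagreed (0.34 and -0.12). Death receptor and caspase genes had 10 of 18 lower and a median of -0.06 (percentile 15.8), with TNFRSF10C at -0.76 and -0.06 at 2 probe sets. Mesenchymal genes had 5 of 8 lower and a median of -0.17 (percentile 5.25), and CDH11 probe sets disagreed (-0.58 and 0.43). The mesenchymal median was 0.05 (percentile 71.85) over 28 members with no floor, and 0.03 (percentile 50.4) with the median over probe sets.

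Proliferation genes did not stand apart: 21 of 41 were higher and 20 lower, with a median of 0.02 (percentile 73.9) that the uniform shift of median centring put at -0.04, and KIF20A was the farthest at -0.41. Immediate early genes had 12 of 19 lower and a median of -0.09 (percentile 5.68), with EPHA4 at -1.02 and KLF4 at -0.70. The list lay outside the random range with quantile normalization (-0.13, percentile 2.28), loess (-0.13, percentile 2.465) and the floor at the 60th percentile (-0.14, percentile 0.99). With the median over probe sets the list median was 0.06 (percentile 83.3), the log2 difference between the floors. Without members shared with the estrogen receptor list it was -0.07 (percentile 11.05). Wnt and Notch genes were split 9 and 9 with a median of 0.00 (percentile 47.1); the Notch ligand JAG1 was at -1.24 (and -1.50) and NOTCH1 at -0.63, while the Wnt receptors FZD2 and FZD1 were at 0.56 and 0.46. Interferon-stimulated genes had 8 of 13 lower, with a median of -0.14 (percentile 6.24), while IFITM1 was at 0.83; the list was outside the random range with the floor at the 40th percentile (-0.16, percentile 1.89), with that from tissue-restricted genes (-0.15, percentile 1.21) and with the median over detected probe sets (-0.17, percentile 2.08), and inside with the floor at the 60th percentile (-0.06, percentile 22.6). Antigen presentation genes had 7 of 11 lower, with a median of -0.03 (percentile 31.3) that was -0.19 with the floor at the 40th percentile (percentile 0.76) or from tissue-restricted genes (percentile 0.465), outside the random range. HLA-DRB1 was at -1.17, an uncertain value for a gene with near-identical relatives. Hypoxia and glycolysis genes had a median of -0.003 (percentile 61.8), with DDIT4 at -0.67 and PFKFB3 at 0.57. Stress response genes of the unfolded protein and amino acid pathways had 18 of 28 lower and a median of -0.05 (percentile 12.1), led by SLC3A2 at -0.78; with the floor at the 60th percentile the list was at -0.10 (percentile 0.97). Angiogenesis factors had 8 of 13 higher and a median of 0.02 (percentile 67.3), with VEGFB at 0.66; with the median over detected probe sets the list was at 0.23 (percentile 99.79), outside the random range. Growth factor receptors and ligands had 12 of 19 higher and a median of 0.07 (percentile 87.0), with FGFR4 at -0.90 and -0.03 at 2 probe sets; with no floor the list was at 0.16 (percentile 98.5). NF-kB genes had a median of 0.10 (percentile 76.7) over 5 members, with REL at 0.45. Metallothioneins and oxidative stress genes had a median of -0.05 (percentile 21.5) and a mean of the other sign, 0.01, with AKR1C1 at 0.86. Histone genes (0.03, percentile 72.2), ribosomal proteins (-0.02, percentile 57.9) and housekeeping genes (-0.03, percentile 35.1) had medians near 0. The signs of the medians for angiogenesis and histone genes turned with the uniform shift of median centring, those for hypoxia, ribosomal and housekeeping genes under quantile normalization and loess, and that for Wnt and Notch genes under all 3 scalings.

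Markers of other cell types were mostly below the floor. Detected members numbered 0 of 12 endothelial markers, 1 of 17 leukocyte markers (LCP1, 0.22), 2 of 14 fibroblast markers (S100A4 at -0.28 and COL1A1 at 0.08), 0 of 18 cancer-testis antigens and 2 of 70 tissue-restricted genes (MBP at 0.18 and MB at -0.10). The signal ratio of the 3-prime to the 5-prime control probe sets was 1.06 and 1.11 for ACTB and 0.957 and 1.04 for GAPDH, in the arrays labelled empty vector and MMP-14. The 3 HUMRGE control probe sets for ribosomal RNA read 50.1, 30.7 and 39.8 in the array labelled empty vector. They read 20.2, 19.4 and 14.99 in the array labelled MMP-14, where all 3 were below the floor. Of the M27830 controls, for another ribosomal RNA, the 5-prime and middle probe sets were above the floor in both arrays. These read 104 and 206 with the empty vector label and 85.1 and 170 with the MMP-14 label. The 3-prime one was below the floor in both. Over control probe sets whose names carry r2, the Bacillus labelling controls had a median log2 ratio of -0.17, or -0.05 over those above the floor in both arrays. The hybridisation controls of that series had a median of -0.06. The other labelling controls above the floor in both arrays lay between -0.32 and -0.04. The other hybridisation controls lay between -0.09 and 0.16, most of them above 0.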

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

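Probe sets that carry several genes or are unnamed here were outside the comparisons, and 8 of them were at least 2-fold higher in the array labelled MMP-14, which drew attention as a signal in data not used elsewhere. Probe set 213711_at had a log2 ratio of 2.29, reading 122 against 25.1, more than the increase of any named gene above the floor in both arrays. Probe set 210299_s_at had a log2 ratio of 1.61, reading 640 against 210. Of 1198 such probe sets above the floor, 5 were at least 2-fold lower, among them 218559_s_at, unnamed here, at -1.62 (27.4 against 84.5). No test was run on these, and no explanation was tested.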

How the results depend on the processing

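The tests with lists without members shared with the estrogen receptor list and with the median over detected probe sets were chosen after the result was seen; the other settings were planned. Against 24 genes higher and 42 lower, the counts were 51 and 74 with the floor at the 40th percentile, 10 and 27 at the 60th, 67 and 77 with the floor from tissue-restricted genes, 1018 and 1137 with no floor, and 9 and 22 with the floor added as an offset. They were 167 and 174 at 1.5-fold, and 0 and 8 at 3-fold. The higher count was 15 with the median over probe sets and 14 without _x_at and _s_at probe sets, where the lower count stayed within 1.5 times. The 3 scalings gave 21 to 22 higher and 42 to 47 lower, and the median over detected probe sets 20 and 38. Of 4 MMP14 probe sets, 1 was above the floor in the array labelled MMP-14 with the 40th percentile floor and 1 with the tissue-restricted floor, and in both settings it was also above the floor in the array labelled empty vector. Estrogen receptor, luminal, cholesterol, p53 and S100 lists stayed outside the random range in all 13 settings, the first with medians of -0.35 to -0.22. Not every setting could move them. Median centring leaves percentiles as they are, and only the luminal list among these lost members when those shared with the estrogen receptor list were left out. Basal markers were at -0.12 with the median over probe sets. Extracellular matrix genes were at -0.12 with the tissue-restricted floor and -0.24 with no floor, both inside. TGF-beta and SMAD targets were at 0.0626 with the median over probe sets, at 0.0799 with the median over detected probe sets, and reversed to -0.0112 without _x_at and _s_at probe sets. TRIM29 reversed to 0.0626 with the median over probe sets. In that setting undetected probe sets enter at the log2 difference between the floors, 0.0626, which by construction accounts for both of its values. Lists inside the random range that left it under some settings were collagen receptors, interferon-stimulated, antigen presentation, immediate early, stress response, growth factor receptor and angiogenesis genes. Of the 41 named genes at least 2-fold different, 25 were under 2-fold in 55 values, and 380 values kept their side. Of those 55 values, the 20 at the 60th percentile floor are bounds, with a signal below that floor. For the other values the cause was not tested. Signal over background limits dim genes, whose log2 ratios spread most. No paired analysis was possible because each group has 1 array, and leaving out an array was not possible for the same reason.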

Other observations

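The tests of swapped arrays, probe positions, scaling, RNA degradation, labelling controls above the floor, the short gain, chance neighbours and runs of 15 genes were chosen after the result was seen. Some genes outside the named-gene rule, chosen after their values were seen, were also at least 2-fold lower. CRABP2, a retinoic acid carrier, read 601 against 1557 (log2 ratio -1.37). The carbonic anhydrase CA2 was at -1.20, the mucin-type glycosyltransferases GALNT6 and ST6GALNAC2 at -1.26 and -1.02, and the heparan sulfate sulfatase SULF1 at -1.18. The amino acid transporter SLC6A14 was at -1.03. Under 2-fold, BIK and its neighbour TSPO were both at 0.74.

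None of the MMP14 probe sets was above the floor in either array. With arrays swapped between the groups, MMP14 signal would be found in the array labelled empty vector, and 0 of the probe sets were above the floor there. That count decides nothing if the probe sets lie outside the transfected cDNA, and 0 columns with probe set positions were at hand to settle it. Both explanations therefore stay open, as does transgene expression below detection, and each direction here is tied to the labels only.

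Estrogen receptor targets were lower in the array labelled MMP-14. Their median of -0.29 was -0.30 with quantile normalization and -0.31 with loess, which argues against array scaling or an intensity-dependent trend. The highest percentile over those settings was 0. Random lists matched on signal would shift with such a trend, so that percentile decides little. Noise of dim probe sets is argued against by 19 members with signals above 100 in both arrays, of which 16 were lower, with a median of -0.23 at percentile 0. Degraded RNA in one array would alter the 3-prime to 5-prime control ratio, which differed by 0.0902 on the log2 scale. The HUMRGE ribosomal RNA control probe sets, below the floor in the array labelled MMP-14, were at least 2.27-fold, 1.39-fold and 1.80-fold lower there. The M27830 ribosomal RNA controls, where above the floor, differed less, with log2 ratios of -0.29 and -0.27. Among controls named r2, the labelling controls had a median of -0.17 (-0.05 over those above the floor in both arrays) and the hybridisation controls -0.06. Other labelling controls above the floor in both arrays lay between -0.32 and -0.04, and other hybridisation controls between -0.09 and 0.16. A difference in RNA input or labelling therefore stays open. The MMP-14 transfection and the separate derivation of the stable lines also stay open, untested with 1 array per line.

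GALC and SPATA7 lie near each other, and the 4 consecutive detected genes GALC (1.56), GPR65 (0.49, at the floor in the array labelled empty vector), SPATA7 (1.39) and PTPN21 (0.59, and down to 0.14 over 3 detected probe sets) were all higher. A gain of a wider chromosome segment is argued against by the 4 detected genes on each side of that pair, PTPN21 among them, whose median of -0.01 lay at percentile 43.6 among runs of 8 genes. Chance stays open: 1.34% of 10000 shuffled gene orders held such a run, but its length and lower bound were taken from the observed one, so the share decides nothing, and a short gain limited to these 4 genes, with 0 DNA measurements here, and shared regulation stay open too. Across all 6835 adjacent pairs log2 ratios correlated at 0.056 (shuffled orders -0.02 to 0.02). Without pairs whose symbols share their first 3 letters the correlation was 0.0461, still above the shuffled orders. Similar probe sets of gene copies named alike therefore do not account for all of it. Copies with other names were not left out, so a part for them stays open. Segments of altered copy number could give such a correlation and stay open; runs of 15 genes, the only length scanned, stayed within the shuffled extremes, as the highest had a median of 0.31 (shuffled extremes 0.22 to 0.35) and the lowest -0.25 (-0.34 to -0.20).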
